A study of Mus musculus with 3 samples.

How the data were processed

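Bulk RNA-seq libraries from 3 samples of lymphatic endothelial cells of the mouse large intestine (C57BL/6), sorted by flow cytometry, were analysed from 1 deposited table per library. The tables hold TPM values per the labels, 1 value for each of 24091 genes identified by Entrez ID and symbol. The values of the 3 libraries summed to 999939, 999907 and 999896. The submitters' processing notes name the genome build mm10, Cell Ranger 6.0.1 and HTSeq. These notes do not state how the TPM values were computed or which annotation was used, so both are treated as unknown here. Of the 24091 IDs, 24045 matched RefSeq genes of GRCm38.p6, the assembly that mm10 stands for, and 23343 had the same symbol there. Coordinates come from that annotation, 1-based, and transcript lengths from the longest GENCODE M21 transcript of a symbol.

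TPM keeps no sequencing depth. An estimate was made from 9831 genes with a single RefSeq transcript, whose TPM multiplied by effective length fell on regular steps below 400 for transcripts of over 1000 bases. The phase score of the steps was 0.533, 0.536 and 0.576 in replicates 1, 2 and 3, against 0.0988, 0.0989 and 0.116 with shuffled lengths. Of the low genes, 66.8%, 67.1% and 69.3% lay within 0.15 of a whole number of fragments, where a tolerance of this width gives 30% by chance. The single-transcript genes carried 49.2%, 47.2% and 47.6% of TPM. The depth is thus an estimate from the values. No interval for counting error was computed from them.

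The 3 libraries form 1 group, so no test between groups could be made. Before the data were examined, 34 gene lists, the 5 list differences, the tests, the rule for named genes and most alternatives were fixed. The rule names all sort marker, lymphatic identity, capillary, collector and valve, niche factor and sex-linked genes. It also names the 5 members of highest mean TPM in every other list, any member of another cell type's list at a mean TPM of 10 or more, the 20 most abundant genes other than ribosomal protein and mitochondrially encoded genes, and the 20 genes with the largest SD of log2(TPM + 1) at a mean TPM of 10 or more. A few genes that this rule covers are not reported here. A few further genes, and the ratios between single genes, were chosen after their values were seen: Flt1, Ackr1, Ptprc, Il7 and the CCL21 copies Gm1987 and Gm13304, Sparc and Mgp, the epithelial regulators singled out, and the genes named for being highest or lowest in replicate 3. Ccl21a, Trac, Igha, Igkc, Hba-a1, Hbb-bt and Muc16 were not found by symbol in the table and were left out of their lists. The lists overlap in places: Lyve1 and Pdpn are sort, identity and capillary genes, Mrc1 is on the capillary and macrophage lists, and Reln is on the identity, capillary and niche lists. Flt4, Mmrn1 and Nrp2 are identity and capillary genes too, so Mrc1 is the only capillary gene that is not an identity gene.

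Values were taken as log2(TPM + 1). Folds of list differences are on this scale and understate differences of low genes. A list difference is the mean over the genes of a list minus that over another within a library, leaving out shared genes, with the mean and SD over 3 libraries and an exact two-sided sign-flip permutation test. With 3 libraries this test cannot give a p below 0.25, and with 2 libraries not below 0.5. A gene was called expressed at a TPM of 1 or more in all 3 libraries. Variable genes were those whose SD lay above the percentile 95 of their bin, with 20 bins of mean expression and genes of mean TPM 1 or more. Lists with at least 3 tested genes were compared with other genes by Fisher's exact test, adjusted by Benjamini-Hochberg over 30 lists at 0.05. List deviations of a library were set against 10000 random lists matched on size and expression bin (seed 7). The steps were tested on simulated data: with a shift of 1 on the log2 scale in replicate 3, 96.0% of changed genes were called variable, as were 10 of 10 changed lists and 0 of 10 unchanged lists. A shift of 0.5 gave 52.5% of changed genes. Simulated genes varied independently, with the median SD of their bin, and every gene of a changed list was shifted. The simulation therefore cannot give the rate of calls for lists whose genes vary together.

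Alternatives were a pseudocount of 0.1, other TPM filters (0.5, 5 or the mean), medians in place of means, members of mean TPM 1 or more, lists without the sort markers, TPM rescaled without ribosomal protein genes, median-of-ratios scaling, the percentile 90 for variable genes, and leaving out each replicate. After the data were examined, 3 gene lists were added (epithelial transcription regulators, and fibroblast and macrophage genes outside the fixed lists), as were 2 alternatives for the list differences. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.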

Results

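RNA was sequenced from lymphatic endothelial cells of the mouse large intestine, sorted by surface CD31 (Pecam1), podoplanin (Pdpn) and LYVE1. The series holds 1 group of 3 libraries, called replicates 1, 2 and 3 here, from C57BL/6 mice. The sample labels do not say whether the 3 libraries came from separate animals or preparations, so the spread between them may be technical. Each library listed 24091 genes in TPM, a transcript abundance corrected for length and library size, and 12862 genes reached a TPM of 1 or more in all 3. Values below are means ± SD over the 3 libraries (n = 3) in TPM unless another unit is named, and coordinates are those of mm10. TPM carries no sequencing depth, but low values of single-transcript genes fell on regular steps. From these steps, a TPM of 1 on 1000 effective bases was estimated to stand for 32.6, 28.2 and 26.2 fragments in replicates 1, 2 and 3. With 1 group there was no comparison between conditions, and the comparisons below set groups of genes against each other within each library.

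The sort markers came first, as a check on the cells collected. Lyve1 (Entrez 114332, chromosome 7, 110850607 to 110862953) averaged 489.6 ± 156, Pecam1 (Entrez 18613, chromosome 11, 106654213 to 106715281) 109.7 ± 7.43 and Pdpn (Entrez 14726, chromosome 4, 143267409 to 143299564) 82.4 ± 23.3. Other genes of lymphatic identity followed, with Mmrn1 at 336 ± 114, Reln at 277 ± 84.6, Sox18 at 81.3 ± 16.1 and Flt4, which encodes VEGFR3, at 73.5 ± 20.5. Tbx1 stood at 46.0 ± 12.9, Maf at 37.1 ± 7.48, Nr2f2 at 29.6 ± 3.96 and Nrp2 at 26.3 ± 2.84. Prox1 (Entrez 19130, chromosome 1, 190118035 to 190170827), the transcription factor that specifies lymphatic endothelium, was the lowest of the list at 3.58 ± 1.12. The median of the other 10 lymphatic identity genes lay 26.8-fold, 17.6-fold and 20.3-fold above Prox1 in replicates 1, 2 and 3. All 11 genes of the list that the table holds reached a TPM of 1 in every library, and their median was 73.0 ± 19.9.

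Blood vessel endothelium also carries CD31, so blood endothelial genes were compared with the lymphatic list. Aqp1 (199 ± 13.8), Car4 (194 ± 82.8), Gpihbp1 (153 ± 55.8), Emcn (129 ± 38.1) and Plvap (107 ± 64.4) were the most abundant of the 18 blood endothelial genes. Podxl (68.4 ± 9.52), Rgcc (43.4 ± 2.28), Efnb2 (29.0 ± 6.33), Dll4 (26.2 ± 1.66) and Vwf (10.7 ± 7.11) came next. Flt1 reached 5.76 ± 5.39 and Ackr1 7.43 ± 6.90. These levels do not assign a listed gene to blood endothelium, since the libraries also held abundant lymphatic and epithelial transcripts. The list's median was 17.6 ± 3.48, and 15 of its genes reached a TPM of 1 in all 3 libraries. The lymphatic list exceeded it by 1.92 ± 0.77 on the log2(TPM + 1) scale, a 3.78-fold difference. The difference was 2.17, 2.53 and 1.06 in replicates 1, 2 and 3, above 0 in 3 of 3 libraries. The exact sign-flip permutation test (two-sided) gave p = 0.25, the smallest value that 3 libraries allow, and 0.25 after Benjamini-Hochberg adjustment over the 5 list differences. The same p of 0.25, raw and adjusted, came from this exact test for each of the other list differences below. Genes shared by endothelium of all kinds were led by Cldn5 (309 ± 97.8), Ecscr (205 ± 74.4), Egfl7 (201 ± 44.4), Ramp2 (189 ± 33.3) and Pecam1, and all 16 of that list reached a TPM of 1 in every library, with a median of 40.7 ± 4.38.

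Epithelial genes were more abundant than lymphatic genes in every library. Car1 averaged 4737 ± 1613, Krt8 3760.2 ± 386, Lgals4 3590.1 ± 233, Krt19 3456 ± 135 and Phgr1 1844 ± 177. Tff3 (1312 ± 242), Epcam (1142 ± 36.7), Cldn7 (863 ± 41.4), Muc2 (814 ± 181), Fcgbp (619.8 ± 24.1) and Krt18 (483 ± 40.1) also lay near or above the level of Lyve1. Cdh1 stood at 247 ± 43.6, Krt20 at 246 ± 72.6, Vil1 at 212 ± 36.6, Slc26a3 at 94.5 ± 35.7, Aqp8 at 72.5 ± 42.6 and Chga at 20.1 ± 6.94, and the stem cell gene Lgr5 was the lowest of the 18 at 3.01 ± 0.301. The lymphatic list minus the epithelial list was -2.76 ± 0.53 (log2), with -2.42, -2.49 and -3.37 in replicates 1, 2 and 3, so the epithelial list was 6.79-fold higher. Its 18 genes made up 2.35 ± 0.272% of all TPM, against 0.148 ± 0.0434% for the 11 lymphatic identity genes. The lymphatic share holds neither Ccl21a, which was not listed, nor its abundant copies Gm1987 (7632 ± 3167) and Gm13304 (2316 ± 926), so it is understated. With these copies in place of Ccl21a, the lymphatic minus epithelial difference was -2.17 ± 0.56 (log2). The median epithelial gene, at 701 ± 62.4, lay at percentile 98.3 ± 0.104 of expressed genes, and the median lymphatic gene at 83.9 ± 5.41. The ratio of Epcam to Pecam1, chosen after their values were seen, was 10.5 ± 0.994.

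**Figure D1:**
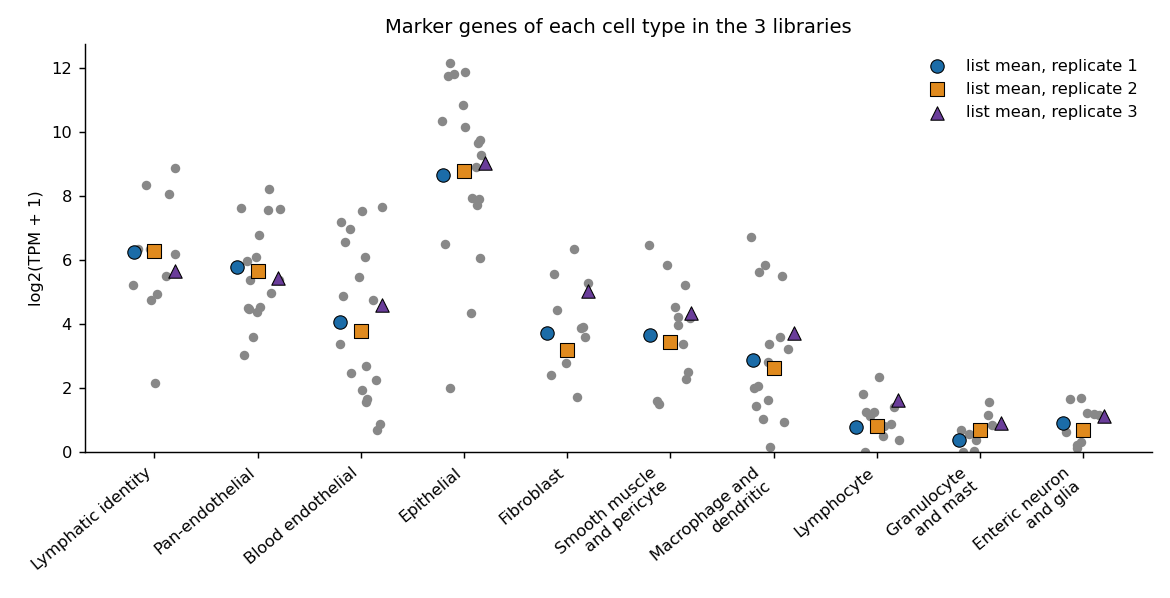
Each grey point is a gene's mean log2(TPM + 1) over the 3 libraries, by cell type list, and coloured symbols are the list mean in each library. The epithelial list lies above the lymphatic identity list in all 3 libraries (6.79-fold on average), and the lymphatic list lies above the blood endothelial, fibroblast, smooth muscle and immune lists.

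Podoplanin is also carried by fibroblasts, and genes of mesenchymal cells were therefore examined. Among fibroblast genes, Dcn averaged 91.5 ± 56.2, Col3a1 58.8 ± 50.4, Dpt 42.2 ± 24.7, Col1a2 24.4 ± 17.8, Col1a1 16.5 ± 12.3, Lum 15.3 ± 9.23 and Tcf21 14.0 ± 12.7. Among genes of smooth muscle and pericytes, Tagln averaged 92.5 ± 35.8, Acta2 63.8 ± 39.0, Actg2 37.1 ± 9.61, Myh11 25.1 ± 15.5, Rgs5 19.7 ± 12.5, Des 17.6 ± 3.66 and Cnn1 14.9 ± 2.52. All 10 fibroblast and all 12 smooth muscle and pericyte genes reached a TPM of 1 in every library, with medians of 16.4 ± 11.6 and 15.4 ± 3.85. The lymphatic list exceeded these 22 genes by 2.17 ± 1.04 (log2), which is 4.50-fold. The difference was 2.55 and 2.97 in replicates 1 and 2 and 0.995 in replicate 3. This last value was smaller than the SD between libraries, which replicate 3 itself widens (0.29 without it).

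Immune genes were compared because some macrophages carry LYVE1. Lyz2 (118 ± 71.4), C1qa (62.8 ± 35.5), C1qc (57.3 ± 42.5), C1qb (51.1 ± 33.8), Mrc1 (11.2 ± 2.69) and Cd68 (10.3 ± 5.47) led the macrophage and dendritic cell list, whose median was 6.49 ± 3.14. The pan-leukocyte gene Ptprc stood at 3.43 ± 2.49. Jchain reached 114 ± 54.2, with Mzb1 at 6.33 ± 4.2, Derl3 at 2.28 ± 0.457 and Tnfrsf17 at 0.795 ± 0.772. Lymphocyte genes were low, led by Cd79a (4.57 ± 2.97), Cd79b (3.29 ± 3.39), Cd4 (1.71 ± 0.542), Nkg7 (1.56 ± 1.02) and Cd3d (1.44 ± 0.525). Granulocyte and mast cell genes were led by Cxcr2 (2.04 ± 0.882), Siglecf (1.28 ± 0.658), Csf3r (0.891 ± 0.589), S100a8 (0.794 ± 1.10) and S100a9 (0.609 ± 0.882). The medians of the lymphocyte, plasma cell and granulocyte lists were 1.11 ± 0.806, 4.31 ± 2.16 and 0.484 ± 0.467. The lymphatic list exceeded the 38 immune genes by 4.09 ± 0.80 (log2), which is 17.1-fold, with 4.56, 4.55 and 3.17 in replicates 1, 2 and 3. Trac, Igha and Igkc were not found by symbol, so the immune level may be understated.

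Genes of further cell types were mostly near the floor. Enteric neuron and glia genes included Uchl1 (2.39 ± 1.38), S100b (1.42 ± 0.757), Gfap (1.31 ± 0.423) and Sox10 (1.31 ± 0.548), and the list median was 1.17 ± 0.398. Mesothelial genes, led by Msln (0.762 ± 0.595), Upk3b (0.340 ± 0.464), Lrrn4 (0.0676 ± 0.0642) and Wt1 (0.0347 ± 0.0341), had a median of 0.210 ± 0.254. The adipocyte list had a median of 0.0932 ± 0.0827, with Cidec at 1.70 ± 0.510, Adipoq at 0.172 ± 0.154, Plin1 at 0.0140 ± 0.0123 and Lep listed at 0 in all 3 libraries. The haemoglobin genes Hba-a2 (290.3 ± 148) and Hbb-bs (196 ± 93.4) and Pf4 (31.2 ± 19.0), listed as a platelet gene, were higher. Itga2b (0.916 ± 0.257) and Alas2 (0.904 ± 0.469) were low, and the median of the erythroid and platelet list was 1.14 ± 0.319. With Itga2b, also listed for platelets, near the floor, the level of Pf4 does not show that platelets were present.

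The title of the series names lymphatic capillaries and collecting vessels, which the libraries do not separate, so marker levels of both vessel types were compared within the pooled cells. Besides Lyve1, Mmrn1, Reln, Pdpn, Flt4 and Nrp2, given above, the capillary list holds Mrc1 (11.2 ± 2.69). Of the collector and valve genes, the connexin genes Gja1 (46.0 ± 8.23) and Gja4 (22.2 ± 5.52) and the genes Clu (23.8 ± 15.7), Esam (23.0 ± 9.11), Fn1 (20.4 ± 7.84), Neo1 (14.8 ± 2.39), Nfatc1 (13.0 ± 1.98) and Celsr1 (11.4 ± 4.13) were among those above 10. Itga9 reached 9.84 ± 1.64, the valve transcription factor gene Foxc2 6.60 ± 2.06 and Gata2 5.75 ± 0.809. Foxp2 (2.04 ± 0.401), Cldn11 (1.47 ± 0.908) and Vangl2 (1.22 ± 0.384) were the lowest, and 13 of the 15 genes reached a TPM of 1 in every library. The capillary list (median 82.4 ± 23.3) exceeded the collector and valve list (median 11.3 ± 0.630) by 3.18 ± 0.30 (log2), which is 9.06-fold, with 3.29, 3.41 and 2.84 in replicates 1, 2 and 3. The capillary genes include the sort markers Lyve1 and Pdpn, and all except Mrc1 are also lymphatic identity genes. The difference therefore sets mainly general lymphatic genes against collector and valve genes. Cells were also sorted on LYVE1 and podoplanin, which favours cells that carry them, so the sort may itself have raised the capillary list. Leaving the sort markers out of the lists (2.77 ± 0.24, log2) does not remove this. A level in pooled RNA does not give the share of cells of either vessel type.

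**Figure D2:**
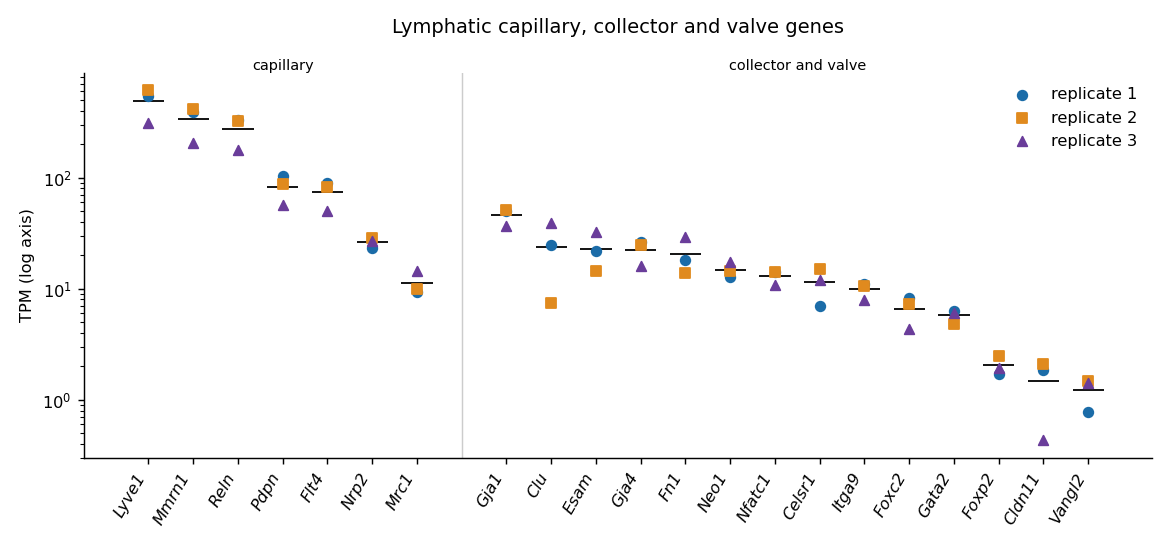
TPM (log axis) of the capillary genes and the collector and valve genes named in the text, with 1 symbol per library and a bar at the mean. Of the 7 capillary genes, Mrc1 and Nrp2 have means within the range of the collector and valve genes, whose highest mean is that of Gja1 at 46.0.

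Signals from lymphatic vessels to the intestinal epithelium are the known subject of studies of this kind, and 46 niche factor genes were examined. Reln (Entrez 19699, chromosome 5, 21884454 to 22344705), which encodes reelin, was the most abundant at 277 ± 84.6, followed by Tgfb1 (42.2 ± 6.54), Il33 (17.1 ± 2.49), Areg (11.2 ± 3.30) and Tgfb3 (11 ± 2.36). Rspo3 (Entrez 72780, chromosome 10, 29453106 to 29535867), the R-spondin gene with the highest value, averaged 5.85 ± 2.22, with 6.24, 7.85 and 3.46 in replicates 1, 2 and 3. Wnt2 averaged 1.30 ± 0.301 and passed a TPM of 1 in 2 libraries. The ratio of Reln to Rspo3, chosen after their values were seen, was 48.5 ± 6.39. In estimated fragments, Rspo3 rested on 586, 644 and 262 and Wnt2 on 104, 81 and 53 in replicates 1, 2 and 3.

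Of the 46 niche genes, 19 reached a TPM of 1 in all 3 libraries, 14 stayed below it in all 3 and 13 lay between. All 8 BMP and TGFB ligand genes were among the 19, with Bmp2 at 9.94 ± 2.86, Bmp4 at 8.71 ± 5.55, Tgfb2 at 6.71 ± 2.17, Bmp6 at 3.84 ± 1.07, Bmp7 at 3.43 ± 0.875 and Bmp5 at 2.63 ± 2.17 (list median 6.87 ± 0.298). The EGF family added Tgfa (9.06 ± 2.45), Hbegf (8.98 ± 2.23), Btc (2.79 ± 0.434) and Egf (2.01 ± 0.305), while Ereg (1.19 ± 0.597) and Nrg1 (0.359 ± 0.244) were lower (list median 2.79 ± 0.434). Among WNT and R-spondin genes (list median 0.776 ± 0.216), Wnt5a reached 1.68 ± 1.01, Wnt4 1.12 ± 0.773, Wnt6 0.941 ± 0.119, Wnt11 0.923 ± 0.328 and Wnt2b 0.907 ± 0.418. Rspo1 (0.214 ± 0.30), Wnt9b (0.119 ± 0.00847), Wnt3 (0.0751 ± 0.101) and Rspo2 (0.0364 ± 0.0320) were low, and Rspo4 was listed at 0. The WNT inhibitor genes Dkk3 (7.40 ± 2.28) and Sfrp1 (4.01 ± 2.26) passed the threshold, and Sfrp5 (1.27 ± 0.345), Sfrp2 (1.11 ± 0.928), Wif1 (0.499 ± 0.341), Dkk2 (0.447 ± 0.153) and Dkk1 (0.237 ± 0.0414) followed (list median 0.950 ± 0.675). No BMP antagonist gene reached a TPM of 1 in all 3 libraries, with Grem1 at 0.737 ± 0.119, Chrd at 0.713 ± 0.335, Chrdl1 at 0.403 ± 0.240 and Nog at 0.350 ± 0.116 (list median 0.620 ± 0.120). Igf1 (1.81 ± 1.32), Hgf (0.834 ± 0.365), Fgf7 (0.634 ± 0.465), Ptgs2 (0.30 ± 0.366) and Fgf10 (0.194 ± 0.0674) completed the list of other niche genes, in which Ptgs2 encodes an enzyme of prostaglandin synthesis and not a secreted factor (median 0.854 ± 0.365). These values describe the whole libraries, in which epithelial genes were abundant, and do not assign a factor to a cell.

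**Figure D3:**
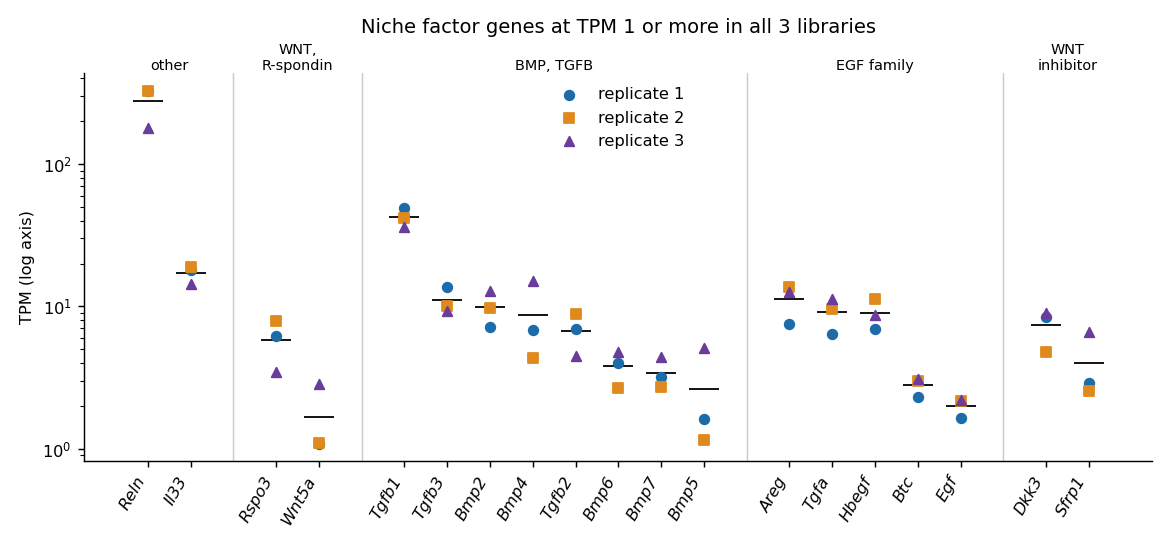
TPM (log axis) of the niche factor genes at a TPM of 1 or more in all 3 libraries, grouped by family, with 1 symbol per library and a bar at the mean. Reln lies above every other gene shown in all 3 libraries, and Rspo3 is lowest in replicate 3.

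Genes of chemokine and leukocyte traffic were examined next. Ccl21a, the chemokine gene typical of lymphatic endothelium, has near-identical copies in the mouse genome and was not listed itself. The copy Gm1987 averaged 7632 ± 3167 and the copy Gm13304 (older symbols Ccl21b and Ccl21c) 2316 ± 926, and reads could have been split between such copies, so their single values are uncertain. Ackr3 (140.4 ± 33), Spns2 (41.7 ± 5.32), Cx3cl1 (29.7 ± 6.69), Cxcl12 (27.2 ± 13.8) and Ackr2 (25.8 ± 8.27) were the most abundant of the 17 other genes, 15 of which reached a TPM of 1 in every library (median 5.38 ± 0.613). Il7, a further gene of this list, averaged 23.0 ± 7.58.

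Further lists of vessel and general cell functions were examined. Their values describe whole libraries in which the epithelial list was 6.79-fold above the lymphatic list, and do not show expression in vessel cells. Lipid handling was led by Apoe (283 ± 131), Cav1 (233 ± 49.3), Fabp4 (91.8 ± 49.4), Plin2 (78.9 ± 14.9) and Cpt1a (76.4 ± 23.1), with 13 of 13 genes at a TPM of 1 in all libraries (median 44.2 ± 4.23). Junction and barrier genes were led by Ctnnb1 (440.3 ± 14.8), Cldn5, F11r (164 ± 9.29), Ctnnd1 (93.4 ± 27.5) and Jup (79.1 ± 5.96), with 11 of 11 (median 47.5 ± 5.49). Of 18 VEGF and angiopoietin pathway genes, 14 passed (median 16.1 ± 1.69), led by Ramp2, Flt4, Tie1 (68.3 ± 12), Vegfb (35 ± 0.430) and Kdr (30.4 ± 2.05). Of 16 flow and mechanosensing genes, 13 passed (median 8.63 ± 1.20), led by Klf4 (203 ± 45.4), Klf2 (80.6 ± 8.29), Orai1 (24.7 ± 1.22), Nfatc1 and Celsr1. The Notch list was led by Hes1 (115 ± 22.2), Dll4, Hey1 (19.7 ± 5.55), Notch1 (15.1 ± 0.930) and Rbpj (11.2 ± 2.25), with 10 of 11 (median 9.93 ± 1.45). Basement membrane genes were led by Col18a1 (60.6 ± 10.7), Col4a1 (54.1 ± 4.37), Lama4 (32.3 ± 6.69), Col4a2 (28.7 ± 5.30) and Hspg2 (24.9 ± 3.98), with 12 of 12 (median 22.2 ± 2.13). Antigen presentation was led by B2m (1652 ± 80.4), H2-D1 (1137 ± 27.3), H2-K1 (989 ± 29.6), Cd74 (279 ± 129.5) and H2-Ab1 (127 ± 62.8), with 10 of 11 (median 127 ± 62.8). Dissociation stress genes were led by Hspa1b (397 ± 107), Jund (325 ± 30.6), Hspa1a (264 ± 65.1), Ier2 (181 ± 8.01) and Jun (138 ± 30.1), with 15 of 15 (median 67.3 ± 3.98), and the design has no undissociated sample to compare them with. Proliferation genes were led by Pcna (206 ± 10.1), Plk1 (65.2 ± 14.4), Birc5 (57.6 ± 7.54), Tyms (43.7 ± 5.69) and Top2a (41.6 ± 5.80), with 16 of 16 (median 28.9 ± 2.23).

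The most abundant gene of the table was Mir6236 (chromosome 9, 110281287 to 110281409), at 50818 ± 1536, or 5.05%, 4.95% and 5.25% of all TPM in replicates 1, 2 and 3. It is annotated with 123 bases, which makes its TPM sensitive to length correction. Without ribosomal protein genes, the next most abundant included Mptx1 (8091 ± 1900.5), Gm1987, Spink4 (7616 ± 1731), Lypd8 (6614 ± 1152), Eef1a1 (5954 ± 140.0), Tpt1 (4777 ± 416), Car1 and Agr2 (4295 ± 186). Krt8, Lgals4, Tmsb4x (3522 ± 437), Krt19, Fau (3448 ± 352), Ppia (3249 ± 224), Guca2a (2925 ± 218), Cox6a1 (2744 ± 106), Klk1 (2662 ± 357) and Ftl1 (2630.2 ± 132) were also among the 20 highest. The 94 ribosomal protein genes took 22.2%, 19.1% and 18.4% of TPM. Y-linked Eif2s3y (38.1 ± 4.33), Ddx3y (18.1 ± 2.22), Kdm5d (9.84 ± 3.09) and Uty (6.91 ± 2.09) were present in all 3 libraries (median of the 5 sex-linked genes 9.84 ± 3.09), and Xist was at 0.0607 ± 0.0270.

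The 3 libraries were then compared with each other, gene by gene. Fibroblast genes differed most between libraries as a group: Col3a1 was at 37.8, 22.3 and 116 in replicates 1, 2 and 3, and Tcf21 at 7.70, 5.70 and 28.7. All 10 fibroblast genes were highest in replicate 3, by a median of 1.02 above the mean of the 3 libraries (log2, SD between genes 0.17). Lymphatic identity genes went the other way, and 10 of 11, among them Lyve1, Reln, Flt4 and Prox1, were lowest in replicate 3 (median -0.48). Of the genes of mean TPM 1 or more, 22.4% were lowest and 41.3% highest in replicate 3. Blood endothelial genes were higher in replicate 3 by a median of 0.67 (SD between genes 0.65), but parted: Flt1, Plvap, Sox17, Gja5, Ackr1, Selp, Vwf, Car4, Esm1 and Madcam1 were highest in replicate 3, and Aqp1, Dll4, Rgcc, Gpihbp1, Podxl and Emcn were lowest. Replicate 3 was also higher for macrophage and dendritic cell genes (median 0.67), lymphocyte genes (0.67), plasma cell genes (0.64) and smooth muscle and pericyte genes (0.55), and higher by less for dissociation stress genes (0.15, with 10 of 15 highest in replicate 3) and epithelial genes (0.14). Proliferation genes were lower (-0.11). Capillary genes, which except for Mrc1 are also identity genes, were lower (-0.50). Pan-endothelial genes were lower too (-0.15), among which Esam alone was highest in replicate 3. For the fibroblast, blood endothelial, macrophage and smooth muscle lists this median lay at percentile 100 of 10000 random lists of the same size and expression, for the epithelial list at percentile 99.99, for the dissociation stress list at 99.52, for the proliferation list at 0.01, and for the lymphatic identity and capillary lists at percentile 0. Each of these deviations describes 1 library and has no replicate. The median deviations of replicate 3 given here had the same sign under median-of-ratios scaling, where the epithelial list was at 0.06 and the dissociation stress list at 0.07, and under rescaling without ribosomal protein genes. Fibroblast genes lay lowest in replicate 2 (-0.79), and plasma cell genes (-0.89) lowest in replicate 1. The median of the 3 erythroid and platelet genes tested was also lowest in replicate 1 (-0.98). It followed Hba-a2 and Hbb-bs, while Pf4 was lowest in replicate 2 (26.3, 15.1 and 52.1 in replicates 1, 2 and 3). The medians of the fibroblast and the macrophage and dendritic lists (-0.50 for the latter) were also lowest in replicate 2.

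Among niche factors, Reln, Rspo3, Wnt2, Tgfb1, Tgfb2, Tgfb3 and Il33 were lowest in replicate 3. So were most lymphatic identity genes, against 22.4% of all genes of mean TPM 1 or more. Bmp2, Bmp4, Bmp5, Bmp6, Bmp7, Wnt4, Wnt5a, Dkk3, Sfrp1, Sfrp2, Sfrp5 and Igf1 were highest in replicate 3, except for Dkk3 under median-of-ratios scaling. The fibroblast genes, 13 of 14 macrophage and dendritic genes and 41.3% of all genes were highest there too. The EGF family genes Egf, Ereg, Btc and Tgfa were highest in replicate 3 as well, with a median deviation of their list of 0.15. Wnt4, Sfrp2 and Ereg reached a TPM of 1 only in replicate 3. The order of the libraries does not assign a factor to a cell type. Of the collector and valve genes, Foxc2, Nfatc1, Itga9, Gja4, Gja1 and Cldn11 were lowest in replicate 3, and Esam, Clu, Neo1 and Fn1 highest.

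**Figure D4:**
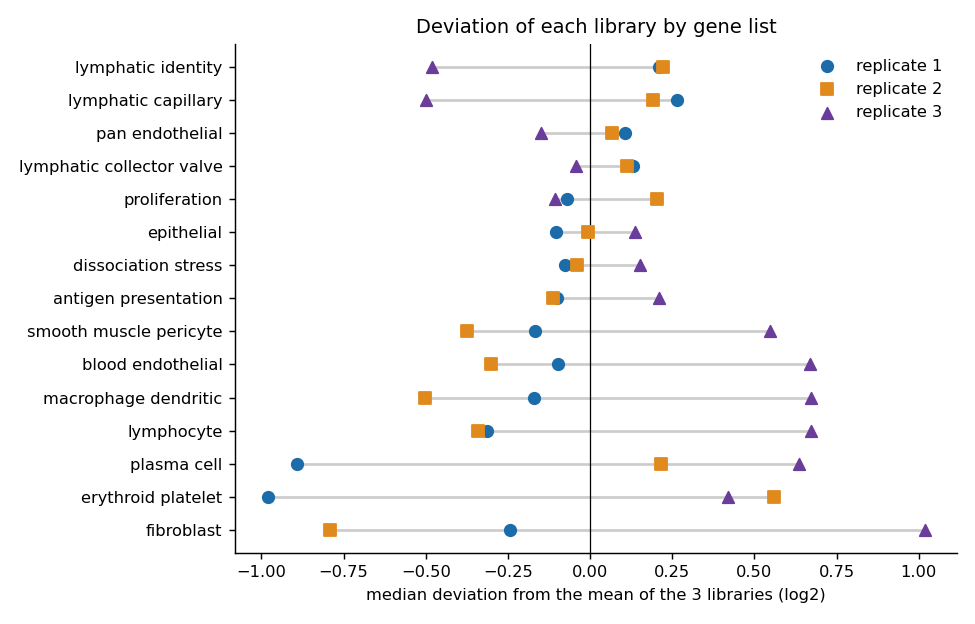
Median deviation of each library from the mean of the 3 libraries (log2), by gene list, with 1 symbol per library. Replicate 3 lies at -0.48 for lymphatic identity genes and at 1.02 for fibroblast genes, with the epithelial list at 0.14.

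Of 13606 genes of mean TPM 1 or more, 680 were called variable for their expression level, and 13 of 30 lists held more of them than other genes did (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p below 0.05). The fibroblast list had 9 variable genes of 10 (0.50 expected, adjusted p = 5.3e-10 by Fisher's exact test), the blood endothelial list 8 of 17 (9.12e-06), the lymphatic identity list 6 of 11 (4.45e-05) and the capillary list 5 of 7 (4.45e-05). The calls of the identity and capillary lists are not separate results, since all capillary genes except Mrc1 are on both. The macrophage and dendritic list had 6 of 14, the erythroid and platelet list 3 of 3, the smooth muscle and pericyte list 5 of 12, the epithelial list 5 of 18, antigen presentation 4 of 11, lipid handling 4 of 13, plasma cells 2 of 3, sort markers 2 of 3 and junctions 3 of 11. No proliferation (of 16), flow (of 15), basement membrane (of 12) or Notch (of 10) gene was variable. At an unadjusted p below 0.05 the exact test named 16 lists. Genes are not independent replicates, and the calls rest on replicate 3: without it, 2 lists (epithelial, erythroid and platelet) were called. The 20 most variable genes of mean TPM 10 or more were Mir343, Snora30, Mir690, Snora75, Hbb-b2, Snord2, Mir2861, Snord58b, Mir7035, Hoxa6, Zbed6, Col3a1, Foxn3, Clu, Tcf21, AF357399, Snora5c, Arl5b, Insl5 and Htra1. Hbb-b2 was at 10.1, 60.3 and 46.9, Hoxa6 at 2.92, 17.5 and 15.2 and Insl5 at 40.7, 14.6 and 66.2 in replicates 1, 2 and 3.

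Across the 12862 expressed genes, Spearman's rho between libraries was 0.980 (replicates 1 and 2), 0.973 (1 and 3) and 0.984 (2 and 3), and Pearson's r of log2(TPM + 1) was 0.984, 0.979 and 0.986. These correlations are across genes, which are not independent replicates. Between 273 and 456 genes differed by more than 2-fold in a pair of libraries, and 49 had an SD above 1 on the log2 scale. Replicate 1 was lower for long transcripts: the median deviation of the 4678 genes with a transcript of over 4000 bases was -0.24 in replicate 1, 0.13 in replicate 2 and 0.13 in replicate 3.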

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

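The alternatives with the CCL21 copies and with the shortened blood endothelial list were chosen after the data were examined, and the others before. Under 46 alternatives the 5 list differences had the same direction as reported. The lymphatic list exceeded the blood endothelial list by 1.57 to 3.65 (log2), the mesenchymal lists by 1.77 to 2.76 and the immune lists by 3.31 to 5.0, the lymphatic minus epithelial difference ran from -3.27 to -2.17, and the capillary minus collector and valve difference from 2.73 to 4.0. The value of 3.65 came from leaving out 8 blood endothelial genes: Aqp1, Emcn, Gpihbp1, Rgcc, Podxl, Dll4, Efnb2 and Car4. These genes were taken as shared with other cells. Each of them lay above the mean of the list, so the value is higher by construction, although Plvap (107 ± 64.4) was kept. The exact p stayed at 0.25 or, with 2 libraries, 0.5, which says nothing about stability. With a TPM of 0.5 in all libraries 29 niche genes counted as expressed, and with a TPM of 5 only 8, by the construction of the threshold. The lowest rho between libraries was 0.961 among genes of TPM 5 or more, where the range of expression is narrower, and 0.973 to 0.984 when a replicate was left out. Lists with more variable genes than others numbered 2 to 18 when a replicate was left out: 2 without replicate 3, 12 without replicate 2 and 18 without replicate 1, and 12 of the 18 were among the 13 reported. The largest list deviation ran from -0.77 to 0.90 when a replicate was left out. With 2 libraries each deviation has an equal and opposite partner, so its sign carries no direction: the values were -0.76 (plasma cell genes, replicate 1, without replicate 2) and -0.77 (erythroid and platelet genes, replicate 1, without replicate 3). Rescaling without ribosomal protein genes shifted the median of all genes by 0.25, 0.22 and 0.22 (log2) and raised the count of niche genes from 19 to 24. Lists without Ccl21a gave no separate value, since the table does not list this gene. No paired analysis was possible because the series has 1 group. Wnt2, at 53 to 104 estimated fragments, lay near the TPM threshold of 1 and missed it in replicate 3, at 0.971, so that it did not count as expressed.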

Other observations

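The tests on transcript length, on mesenchymal and immune genes, on a smaller lymphatic share and on Prox1 were chosen after the results they concern were seen, and those on epithelial regulators and on fibroblast and macrophage genes outside the lists were fixed before their values were seen. The series has 1 group, so no explanation was tested between conditions, and these tests use only values within the 3 libraries.

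The epithelial list lay 6.79-fold above the lymphatic identity list in libraries sorted for lymphatic endothelium, a size that depends on the genes listed. Short epithelial transcripts set against long lymphatic ones were not the reason, since among genes with a longest transcript of 1000 to 3000 bases the epithelial list (11 genes) still exceeded the lymphatic list (4 genes, of which Lyve1 and Pdpn are sort markers) by 2.72 ± 0.60 (log2), and by 2.31 or more in each library. Unsorted tissue in place of sorted cells stays open, since no unsorted sample gives the level of these lists to compare with. The lymphatic list exceeded the mesenchymal lists in every library, in replicate 3 by 0.995. This lay within the SD of 1.04 between libraries, but replicate 3 itself widens that SD, which is 0.29 without it. While the immune lists lay further below (by at least 3.17), Lyz2 (118) and Jchain (114) reached the level of Pecam1 (109.7). Epithelial cells or their RNA in the sequenced material are a candidate source: 8 epithelial transcription regulators outside the lists, led by Cdx1 (397 ± 36.5), Elf3 (297 ± 14.4) and Hnf4a (195 ± 61.5), had a median of 124. Their mean log2(TPM + 1) was 6.23 ± 0.27, close to the 6.07 ± 0.35 of the lymphatic identity list. The sort on CD31, podoplanin and LYVE1 is meant to leave out epithelial cells, but no value here gives its purity. Whole cells and free RNA were not separated by the test on these regulators.

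Replicate 3 was lower for lymphatic identity genes and higher for fibroblast and macrophage genes. A smaller lymphatic share alone would raise the genes of all other cell types alike, but the fibroblast list rose by 0.88 more than the epithelial list, against a summed spread between genes of 0.41. A larger share of fibroblasts and macrophages in replicate 3 is a candidate explanation: 22 genes of these cells outside the lists, such as Sparc (83.0 ± 60.6) and Mgp (83.3 ± 63.1), had a median deviation of 0.83 (SD 0.39), and 20 of them lay above 0. The sort on CD31, podoplanin and LYVE1 is meant to leave out both cell types, but no value here gives its purity. Genes of the same cell type can vary together, so these 22 genes give no support independent of the lists. The blood endothelial (0.67) and smooth muscle and pericyte (0.55) lists also had median deviations above 0 in replicate 3. Of their genes, 6 of 17 and 1 of 12 were lowest there. Endothelium or pericytes of blood vessels in the same library were not tested on genes outside the lists and stay open. Whether such a difference arose in the tissue, the dissociation or the sort stays open, and dissociation stress genes were also higher in replicate 3, by a median of 0.15, or 0.07 under median-of-ratios scaling.

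Prox1 lay far below the other lymphatic identity genes, at 3.58 ± 1.12 against 23.3 or more for each other gene of the list in every library. Reln has a longer transcript (11699 bases, against 7913 for Prox1), and its lowest value was 179. A long transcript alone thus did not keep a gene of this list low. This comparison rests on 1 gene whose level in the cells is not known. It cannot decide whether transcript length or a bias toward transcript ends lowered Prox1. Prox1 rested on an estimated 822, 1053 and 533 fragments in replicates 1, 2 and 3, so its low value was not a matter of depth. A low level of this transcript in the cells themselves, and reads lost to how the authors assigned them to Prox1, stay open as untested.

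Replicate 1 differed from the others along transcript length. Across 13370 genes of mean TPM 1 or more, Spearman's rho between a gene's deviation and its longest transcript was -0.430 in replicate 1, 0.351 in replicate 2 and 0.264 in replicate 3, a relation across genes, which are not independent. Ribosomal protein genes, with a median longest transcript of 1043 bases, took 22.2% of TPM in replicate 1 and 19.1% and 18.4% in replicates 2 and 3. Single genes did not all follow the trend: of the most variable genes, Zbed6 (5007 bases, at 3.11, 17.4 and 15.3 in replicates 1, 2 and 3) and Hoxa6 (874 bases, at 2.92, 17.5 and 15.2) were both lowest in replicate 1, and Col3a1 (5564 bases, at 37.8, 22.3 and 116) was not.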
